A study of Sus scrofa with 10 samples.

How the data were processed

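The series holds 10 RNA-seq libraries from 60-day-old Northeast Min pigs: 1 library from each of 9 tissues and 1 from a pool of tissues. According to the labels, total RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit. The submitters' processing notes name TopHat2 2.1.0, StringTie 1.2.2 and the assembly Sscrofa11.1. What each step did, the annotation release, strandedness and any filter are not given in the sources used here. The deposited table has 1 value per gene and library, and its values were read as FPKM. That unit is not named in the header. It was inferred from non-integer values with sums of 292495 to 369254 per library and from StringTie being named, so a related unit scaled within each library cannot be excluded. No counts were used, so no count model or test was run, and the depth of each library is known only from the spacing of values in short genes (genes spanning 400 to 1500 bp, steps matched within 1%).

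Each of the 10 columns was used, and none was left out. Each library was its own group, because the labels give no replicate. Gene symbols came from a table of Ensembl identifiers (14857 genes) and, where that gave none, from the RefSeq gene on the same assembly that overlapped reciprocally by at least 0.5 of the longer gene and was the best match both ways (1640 genes). This named 63.7% of the genes. For the 12554 genes named in both ways, 95.1% of names were equal. Where several genes shared a symbol, the one with the highest mean over the 10 libraries stood for it. Gene models that contain or overlap another named gene were listed, since their value can include the neighbour.

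A gene was detected at 1 FPKM or more. Levels were compared as log2(FPKM + 1). The pair of skeletal muscles was averaged into 1 class, giving 8 classes, and a gene was enriched in a class when FPKM + 1 was at least 5-fold above that of every other class, with at least 1 FPKM. Libraries were compared by Spearman's rho over genes at 1 FPKM or more in at least 1 library. Psoas major and longissimus dorsi were compared over genes at 1 or more in either, with a threshold of 1 on the log2 scale. Heart was compared with the mean log2 level of the muscles, with a threshold of 2 that had to hold against each muscle. The pool was fitted by non-negative least squares on the 8 classes, each gene divided by its mean over the 10 libraries plus 1, with weights scaled to sum to 100%, and genes that departed from the fit by 1 or more on the log2 scale were counted. The robust SD is 1.4826 times the median absolute deviation.

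58 gene lists were fixed before the data were examined, as were the comparisons, the thresholds and the rule for named genes. A list member was tested only if it reached 1 FPKM in at least 1 of the 10 libraries. In the muscle comparisons it had to pass the filter of that comparison, which for heart was 1 FPKM in heart or in both muscles. The median of the tested members was placed among 10000 random lists of the same size, drawn from genes matched on mean level in 20 bins with seed 1. Such a percentile describes these libraries and is not a test across animals. The rule named members of the gene lists, the 8 most abundant enriched genes per class, the 3 highest genes per library, the 10 genes with the largest difference each way in either muscle comparison (at 5 FPKM or more on a side) and the 5 genes with the largest departure each way in the pool. The genes of a single tissue in the pool were selected after the data were seen, as were the counts of values at 0, and the lists of nervous system, Schwann cell, testis, gut, pituitary, thyroid and thymus markers used on the pool were written then too.

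Alternatives varied the pseudocount (0.1 and 5), the filter on low values, the detection level, the fold and difference thresholds, the scaling (to a sum of 1000000, to the mean sum, by median-of-ratios factors, by quantiles and by centring on the median), the treatment of the muscles, the statistic of the lists and the form of the pool fit. The procedures were tested on simulated data with noise of 0.2 on the log2 scale. The real comparisons spread more, with robust SDs of 0.36 between the muscles and 0.57 between heart and muscle. Their medians were offset by 0.27 and 0.41, so the following values describe the simulation only. In the muscle pair, 17.9% of 2-fold and 98.5% of 4-fold changes were recovered. Between heart and muscle, 5.97% of 4-fold and 85.1% of 8-fold changes were recovered. All 10-fold enriched genes were recovered. Apart from the 200 changed genes, none of the 10051 genes of the muscle pair, 10630 of heart and muscle and 13377 of the enrichment was called. The pool weights were off by at most 0.227 percentage points. Of unchanged lists, 6.50% fell outside the central 95% of random lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.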

Results

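RNA abundance was measured once in each of 10 libraries from 60-day-old pigs of the Northeast Min breed. 9 libraries came from single tissues, namely heart, liver, spleen, lung, kidney, psoas major, longissimus dorsi, subcutaneous adipose tissue and ovary. The last library came from a pool that is labelled as a mixture of heart, liver, spleen, lung, kidney, muscle and ovary, with adipose tissue not among them. Each tissue had 1 library, so no difference between tissues has a replicate check, and no p-value or error is given. The deposited table lists 25880 genes of the pig assembly Sscrofa11.1, with values that behave as FPKM. The summed FPKM of a library ran from 292495 in kidney to 369254 in longissimus dorsi. Sequencing depth is not stated in the sources used here. Regular steps in the values of short genes put it between 11.5 M fragments (psoas major and kidney) and 31.5 M (lung), uncertain by a factor of 2.

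The most abundant transcripts in heart were TNNC1 (9656 FPKM), TNNT2 (9493) and MYL3 (8244), which encode parts of the cardiac contractile apparatus. Liver was led by ALB, the gene of serum albumin (ENSSSCG00000008948, chromosome 8, 69531487 to 69681699), at 30453 FPKM or 9.01% of the library, followed by APOC3 (12043) and TF (9489). Lung was led by the surfactant protein gene SFTPC (6562), and kidney by the ferritin gene FTL (5733) and the antioxidant gene GPX3 (3593). In both skeletal muscles GAPDH, MYL11 and ACTA1 ranked highest. GAPDH alone took 5.01% of the psoas library (15923 FPKM) and 9.36% of the longissimus library (34563 FPKM). In spleen, adipose tissue and ovary the highest value was that of ENSSSCG00000004489, a gene model on chromosome 1 that spans EEF1A1 and MTO1, at 5919, 5100.1 and 5743 FPKM. It was followed by TMSB4X (3520.4) and HBB (3102) in spleen and by COL3A1 (5000.3) and FABP4 (4919) in adipose tissue. In ovary it was followed by COL3A1 (2289) and by a gene model inside EEF1A1. The 10 highest genes held 35.0% of the longissimus library, 24.9% of liver, 24.4% of psoas and 17.9% of heart, but 7.23% of ovary and 8.50% of spleen.

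The series was described as a resource for pig gene annotation, so the breadth of expression was counted first. At 1 FPKM or more, 15637 genes were detected in at least 1 of the 9 tissues, and 5612 genes were at 0 in all 10 libraries. Ovary had the most detected genes (13164), followed by lung (12788), and longissimus dorsi the fewest (9592). All 9 tissues shared 7665 genes (49.0% of those detected), and 1703 genes (10.9%) were detected in exactly 1 tissue. Of the genes detected in exactly 1 tissue, ovary held 708, lung 284, spleen 218, kidney 200, liver 144, adipose tissue 68 and heart 54. Psoas major held 17 and longissimus dorsi 10. A gene found in both muscles was not counted, and with the muscles merged 1773 genes were detected in exactly 1 tissue. A detection level of 5 FPKM lowered the genes shared by all tissues to 2941.

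To ask which genes mark each tissue, the pair of skeletal muscles was merged, which gave 8 tissue classes. A gene was called enriched in a class when its FPKM + 1 was at least 5-fold above that of every other class, with at least 1 FPKM in the class. By this rule 1015 genes were enriched: 236 in liver, 230 in ovary, 162 in kidney, 115 in lung, 97 in skeletal muscle, 67 in spleen, 54 in heart and 54 in adipose tissue. The 236 liver genes held 45.4% of the liver library and the 97 muscle genes 24.98% of the muscle libraries. The 230 ovary genes held 2.62% of the ovary library, with a median of 13.5 FPKM, against a median of 120 FPKM for the liver genes. Pseudocounts of 0.1 and 5 took the ovary count to 538 and 53, and folds of 3 and 10 took it to 506 and 78. Median-of-ratios scaling and quantile normalisation took the ovary count to 151 and 149. Rescaling every library to a sum of 1000000 took it to 442, but that also shrinks the pseudocount relative to the values, and rescaling to the mean sum, added after the data were seen, left it at 239. For gene lists fixed before the data were examined, the median difference between a class and the mean of the other classes is given on the log2 scale. Unless another percentile is given, each such median stood at percentile 99.9 or 100 among 10000 random lists matched for expression level.

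**Figure D1:**
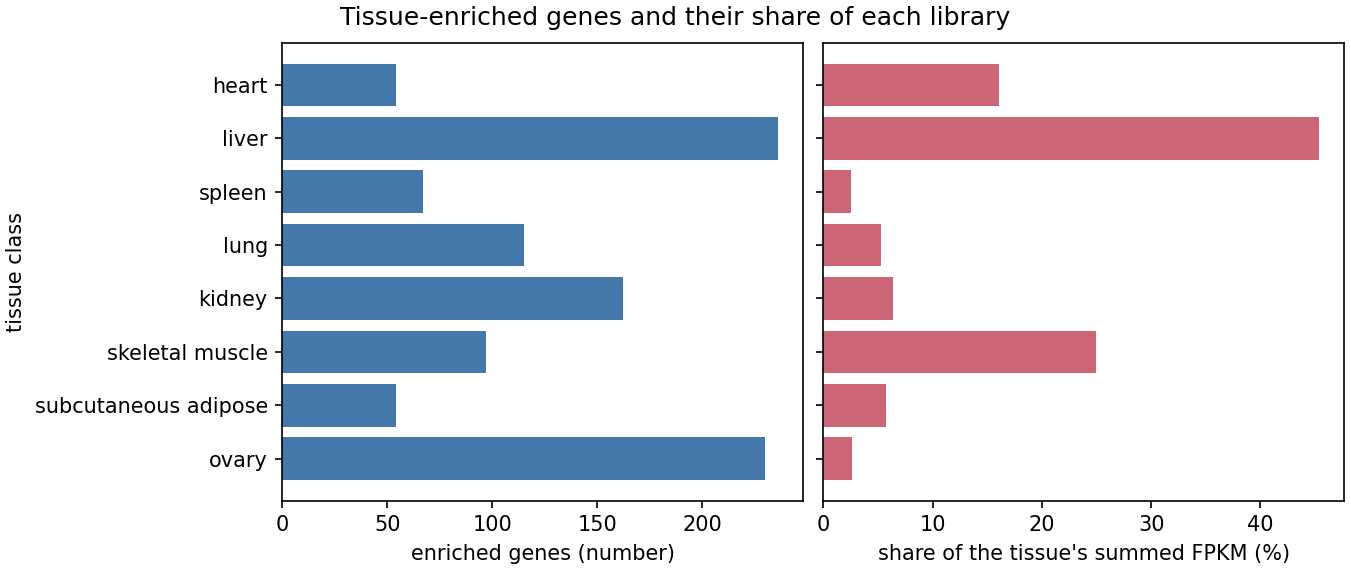
Genes enriched in each of the 8 tissue classes: the left panel gives their number and the right panel their share of the summed FPKM of the class, in percent. Liver and ovary had 236 and 230 enriched genes, which held 45.4% and 2.62% of their libraries.

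Liver was marked by secreted plasma proteins. Of 22 matched members of the plasma protein list, the 21 that were tested were all enriched there, with a median of 2261 FPKM and a median difference of 9.94. APOC3, a lipoprotein component, stood at 12043 FPKM against 51.6 in kidney, the next class, and AHSG at 4636 against 14.9 in adipose tissue. Of 15 complement and acute phase genes, 14 were highest in liver, and C3, the central complement component, reached 3164. Of 12 genes of the urea cycle and amino acid breakdown, 10 were highest in liver, among them CPS1 (205) and OTC (154), enzymes of the first steps of the urea cycle. ASS1, which acts later in that cycle, was instead highest in kidney (1745, against 590.0 in liver). The bile salt ligase gene SLC27A5 stood at 249 and the drug-metabolising CYP2E1 at 1021, while CYP7A1, the rate-limiting enzyme of bile acid synthesis, stood at 6.85 in liver and 39.6 in lung. The fetal liver gene AFP was at 0.222 FPKM. Only 5 of the 13 listed cytochrome P450 genes were matched by name.

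Kidney was marked by transport genes along the nephron. All 16 proximal tubule genes were highest in kidney and 12 were enriched, with a median difference of 7.10. They included LRP2, the endocytic receptor megalin (537 FPKM), the phosphate transporter SLC34A1 (526) and the organic anion transporter SLC22A8 (506). UMOD, which encodes uromodulin of the thick ascending limb, was the most abundant enriched gene (2481 FPKM against 0.277 in ovary), and SLC12A1 and SLC12A3, targets of loop and thiazide diuretics, stood at 252 and 225. Of 11 collecting duct genes 8 were highest in kidney, among them the water channel gene AQP2 (72.4). Of 7 tested gluconeogenesis genes 5 were highest in kidney, with PCK1 at 1524 against 344 and G6PC1 at 298 against 186. The posterior HOX genes HOXA10 (26.5) and HOXD8 (31.9) were also highest in kidney, where that list's median difference was 2.03.

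Lung was marked by alveolar and airway epithelium. 9 of 10 alveolar type 2 genes were highest in lung, with a median difference of 6.48, and SFTPC, SFTPB (1300.5) and SFTPA1 (654) were each under 1 FPKM in every other tissue. AGER, a marker of alveolar type 1 cells, stood at 685, and the club cell genes SCGB1A1 and SCGB3A1 at 962 and 259.6. All 10 tested airway genes were highest in lung, including FOXJ1 (24.2), a regulator of motile cilia. MARCO (336) and CD163 (165), receptors of macrophages, were higher in lung than in spleen (74.2 and 48.9), but of the 15 macrophage genes 7 were highest in lung and 7 in spleen. Of 11 endothelial genes 9 were highest in lung. Of 10 tested immediate early and heat shock genes 7 were highest in lung, with FOS at 105 and EGR1 at 100.1 FPKM against 37.9 and 35.6 in adipose tissue, the next class.

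Spleen was marked by lymphocyte genes at moderate levels. All 14 genes of the B and plasma cell list were highest there, with a median difference of 4.10, among them CD79B (48.7), MS4A1 (35.7) and JCHAIN (1203, against 488 in lung). Of 13 T and NK cell genes 12 were highest in spleen, with LCK, a kinase of T cell receptor signalling, at 56.9. TLX1, a transcription factor needed for spleen formation, stood at 44.953 FPKM and at most 0.153 in the other tissues, and SPIC, a regulator of red pulp macrophages, at 48.1. The macrophage iron genes HMOX1 and SLC40A1 reached 191 and 244. Of 11 erythroid genes 10 were highest in spleen, including AHSP (22.7), the alpha haemoglobin stabiliser, and 12 of 15 cell cycle genes were highest there, with TOP2A at 27.9 and MKI67 at 9.87. The smooth muscle genes TAGLN (488) and ACTA2 (314) were also highest in spleen. VCAM1 (486), the mitochondrial gene ND2 (374, listed at 0 in 8 of the other libraries) and CXCL12 (253) led its enriched genes.

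Adipose tissue combined adipocyte and matrix genes. Of 18 white adipocyte genes 13 were highest there and 8 were enriched, with a median difference of 5.71. The fatty acid binding protein gene FABP4 stood at 4919 FPKM, the hormone gene ADIPOQ at 2074, the lipid droplet gene PLIN1 at 907 and the lipase gene LIPE at 604, whereas LEP was at 2.95. Of 14 fibroblast and matrix genes 11 were highest in adipose tissue, with COL3A1 at 5000.3, SPARC at 3516 and POSTN at 744. CIDEA, a lipid droplet gene on the thermogenic list, reached 792, but PPARGC1A was at 0.0905 and that list did not pass percentile 97.5 there. Of 14 lipid synthesis genes 5 were highest in adipose tissue, among them FASN (52.2) and ELOVL6 (87.4), and 5 in liver, with median differences of 0.86 and 1.05. Liver plasma protein transcripts were present too, at a median of 9.77 FPKM over the 21 tested list members, with ALB at 127.

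Ovary was marked by oocyte and follicle genes. Of 16 tested oocyte genes 15 were highest in ovary and 11 were enriched, with a median difference of 4.07. The zona pellucida genes ZP3, ZP4 and ZP2 stood at 171, 78.4 and 42.8 FPKM, PADI6, a maternal-effect gene, at 148, and the germ cell helicase gene DDX4 at 36.8. Of 12 granulosa genes 9 were highest in ovary, among them INHA (135), AMH (23.9) and FSHR (5.71), which encode an inhibin subunit, anti-Mullerian hormone and the FSH receptor. The theca and steroid synthesis list had a median difference of 2.32, and 4 of its 7 tested genes were highest in ovary, among them HSD17B1 (25.3) and NR5A1 (16.7), although CYP17A1 was at 0.924 and STAR at 4.67. The luteal list did not pass percentile 97.5. The somatic genes FBLN1 (564) and RARRES1 (487) led the enriched genes of ovary, and COL1A1 stood at 1443 against 2284 in adipose tissue.

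Skeletal muscle was marked by fast-fibre and glycolytic genes. All 14 matched fast-fibre genes were highest in muscle and 13 were enriched, with a median difference of 9.95, led by the myosin light chain gene MYL11 (mean of both muscles 12856 FPKM) and the troponin genes TNNI2 (5626) and TNNT3 (4116). All 15 glycolysis genes were highest there, including ALDOA (10908) and ENO3 (8235), whose gene model also overlaps SPAG7. The myogenic regulators MYF6 (12.047) and MYOG (11.095) were enriched in muscle at much lower levels. Heart was marked by 12 of 13 cardiac contractile and natriuretic genes, with a median difference of 9.49. All 20 nuclear genes of the respiratory chain were highest in heart without being enriched, with NDUFA4 at 1921 and ATP5F1A at 1208 FPKM. Of the 36 lists named for a tissue, 33 passed percentile 97.5 in it, and the atrial list in heart was among the 3 that did not. Gene models can merge neighbours: that of MYH6 contains MYH7, and that of FANCE, named among the top spleen genes, contains RPL10A.

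The similarity of whole libraries followed tissue type in part. Across 15768 genes, Spearman's rho was 0.958 between psoas major and longissimus dorsi, 0.877 between heart and psoas major, and 0.832 between spleen and lung. Adipose tissue was nearest to longissimus dorsi (0.8165) and heart (0.816), ahead of lung (0.794). Liver and ovary were the least similar pair, at 0.625. The pool was nearest to liver (0.839) and farther from lung (0.770) and ovary (0.653). Genes are not independent replicates, so these coefficients describe the libraries and carry no p-value.

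Isoforms of the sarcomere were among the largest differences between heart and skeletal muscle. TNNT2, the cardiac troponin T gene (ENSSSCG00000023031, chromosome 10, 23749528 to 23756374), stood at 9493 FPKM in heart against 3.07 in psoas and 3.96 in longissimus. TNNI3 (2045) and MYBPC3 (1086), also cardiac isoforms, were under 1 FPKM in both muscles, and 12 of 13 genes of the cardiac contractile list were higher in heart, with a median difference of 4.13. On the muscle side all 13 tested fast-fibre genes were higher, with a median of -9.96: MYL11 was at 0.227 in heart against 10547 and 15165, and the fast myosin gene MYH4 at 0.00167 against 473 and 1966. SLN, which encodes a regulator of the calcium pump, was listed at 0 in heart and at 1372 and 1528 in the muscles. Of genes for calcium handling, RYR2 (85.1) and CASQ2 (367) were higher in heart, and ATP2A1 and CACNA1S in muscle.

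The metabolic lists separated heart and muscle too. 9 of 15 glycolysis genes were higher in muscle and none in heart, with a median of -2.89, led by LDHA (39.0 FPKM in heart, 1630.1 in psoas) and the glycogen phosphorylase gene PYGM (37.6 against 1432). PYGB, another glycogen phosphorylase gene, was higher in heart (177 against 0.729 and 0.352). The 20 respiratory chain genes all lay above 0 towards heart, with a median of 0.90 and percentile 99.9, though none reached the 4-fold threshold. The fatty acid oxidation list had a median of 0.96, with 17 of 19 genes above 0, none past the threshold towards heart and UCP3 past it towards muscle. Lists of other kinds lay towards heart by as much or more: endothelial (1.14), macrophage (1.06), interferon response (1.06) and erythroid (1.88). The slow-fibre list was divided, with 7 of 12 genes higher in heart, such as MYL3 and LDHB, and 4 higher in muscle, such as TNNI1 and TNNT1. Its median was 2.54 but its mean 0.35. Cardiac transcription factors were higher in heart in 5 of 7 cases, among them TBX20 (19.3), NKX2-5 (15.9) and GATA4 (22.004). The posterior HOX genes went the other way, with 3 of 5 higher in muscle, and HOXD8 stood at 0.101 in heart against 10.6 and 15.2. The genes CCK (253), PCP4 (277) and NEBL (387) were among the 10 largest differences towards heart. The mitochondrial gene COX3 was too, but it was listed at 0 in both muscles, in spleen and in lung.

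By a difference of at least 2 on the log2 scale against each muscle, 336 of 11145 genes were higher in heart and 213 in skeletal muscle. The median of all genes lay 0.41 towards heart, so the respiratory chain and fatty acid oxidation medians were 0.49 and 0.55 above it. The share of these calls that favoured heart was 61.2% as deposited, 48.5% after median-of-ratios scaling (269 and 286 genes) and 43.5% after centring on the median (219 and 284 genes). Pseudocounts of 0.1 and 5 moved the heart count to 589 and 133.

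Psoas major and longissimus dorsi were compared as the closest pair of tissues. Glycolytic transcripts and most matched fast-fibre transcripts were more abundant in longissimus. The median over 15 glycolysis genes was -0.93 (psoas minus longissimus, percentile 0), and 6 passed 2-fold towards longissimus, among them TPI1 (322 against 1491 FPKM), PYGM (1432 against 3994) and GAPDH (15923 against 34563). HK2, which encodes a hexokinase, was the exception, at 23.2 in psoas against 6.43. Of 14 matched fast-fibre genes 13 lay towards longissimus and 5 passed 2-fold, including MYH4 (473 against 1966), ACTN3 (632 against 1786) and TNNT3 (2730.4 against 5501), with a list median of -0.60 at percentile 0.030. MYH1 and MYH2, also among the 16 listed, were not matched by name. The unnamed gene model ENSSSCG00000029441, near MYH4 on chromosome 12, lay towards psoas, at 4870 FPKM against a mean of 3719 over both muscles. Oxidative genes lay towards psoas. The fatty acid oxidation list had a median of 0.66 at percentile 100, with 5 of 19 genes past 2-fold, among them FABP3 (236 against 64.6) and CPT1B (90.9 against 38.2), which admits fatty acids to mitochondria. The respiratory chain list had a median of 0.58 at percentile 99.9, with ATP5F1A at 914 against 417. The slow-fibre list lay at 0.38 (percentile 92.9), and ATP2A2, the slow calcium pump gene, at 329 against 145.

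**Figure D2:**
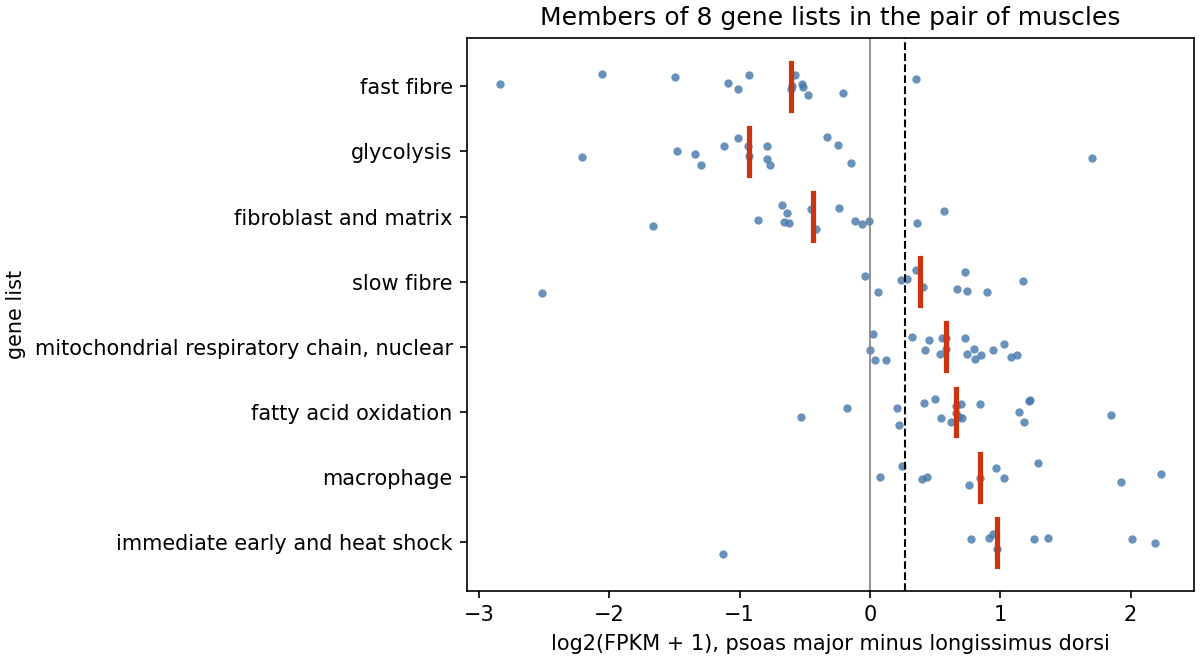
Difference in log2(FPKM + 1), psoas major minus longissimus dorsi (horizontal axis), of each member of 8 gene lists, where each point is 1 gene. Most glycolysis and fast-fibre genes lie to the left, with medians of -0.93 and -0.60, and most fatty acid oxidation genes to the right, with a median of 0.66.

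Lists of other cell types also lay apart between the muscles. Macrophage genes lay towards psoas in all 11 cases (median 0.84), with CD163 at 29.4 against 7.0048, and so did the 4 erythroid genes (median 1.09), with HBB at 198 against 70.1. Immediate early genes had a median of 0.98, with FOS at 10.4 against 1.51. Matrix genes lay towards longissimus in 12 of 14 cases (median -0.43). Liver plasma protein transcripts were higher in longissimus in 13 of 16 cases, with ALB at 24.973 against 0.0864, and 19 of the 220 genes higher in longissimus were liver-enriched. Among the largest differences, the hindlimb transcription factor gene PITX1 was at 14.4 in psoas and listed at 0 in longissimus. TBX1 (21.4 against 0.891), CAV3 (42.0 against 0.275) and SPP1 (22.3 against 0.372) were higher in psoas, and ACTC1, the cardiac actin gene, stood at 217 against 24.1. IGFN1, which encodes an immunoglobulin-like muscle protein, was higher in longissimus (454 against 32.0), as was CAVIN1 (60.0 against 0.440). CAV3 was also low in heart (0.170), whereas CAVIN1 stood at 83.9 there. A failed estimate in the lower muscle was not excluded for CAV3 or CAVIN1. HOXA10 was higher in psoas (8.16 against 0.351), and HOXC9 in longissimus (6.79 against 2.38), but the posterior and anterior HOX lists as a whole lay at percentiles 71.0 and 24.7.

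By a difference of at least 1 on the log2 scale, 490 of 10513 genes were higher in psoas and 220 in longissimus, and the median of all genes lay 0.27 towards psoas. This split depended on scaling. The share towards psoas was 69.0% as deposited, 83.9% after rescaling to the mean sum (815 and 156 genes, added after the data were seen), 84.4% after rescaling to a sum of 1000000, which also shrinks the pseudocount and filter relative to the values (1639 and 304), 40.0% after median-of-ratios scaling (331 and 496) and 36.5% after centring (228 and 397). The direction of every list median given here for these muscles was the same as deposited, at a sum of 1000000, after median-of-ratios scaling and after centring, and relative to the median of all genes the glycolysis, fast-fibre and fatty acid oxidation lists lay at -1.20, -0.88 and 0.39. The oxidative lists shrank: the respiratory chain list lay at 0.25 after median-of-ratios scaling and 0.31 after centring, and the slow-fibre list at 0.05 and 0.11. In the muscle that was lower, 21 of the 490 and 34 of the 220 genes were at exactly 0. A value of 0 can be a failed estimate: among 1384 genes at 20 FPKM or more in at least 7 libraries, 7 were under 0.1 in another. That screen needs a high value in 7 libraries, so it cannot see genes whose estimate failed in most or all of them. The mitochondrial genes KEF22_t15 and ND5, first on either side, were listed at 0 in the lower muscle.

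The pool was compared with the single tissues. Fitted as a weighted sum of the 8 classes, it was 46.3% liver, 18.2% lung, 11.4% spleen, 6.55% skeletal muscle, 6.12% kidney, 5.53% heart, 4.37% ovary and 1.51% adipose tissue. Liver genes dominated it accordingly, with ALB at 14405 FPKM and APOC3 at 6159.7. Among genes of a single class (at least 5 FPKM, all other classes under 2% of it), the 122 liver genes stood in the pool at a median of 47.6% of their liver level. The corresponding medians were 17.1% for 33 lung genes, 14.2% for 11 spleen genes, 6.32% for 41 muscle genes, 5.70% for 49 kidney genes and 3.94% for 13 heart genes. The 9 adipose genes stood at 0.294%. The 90 ovary genes stood at 0.00133%, far under the fitted weight, with 45 of them at 0 and an upper quartile of 0.574%. ZP3 was at 0.0924 FPKM in the pool against 171 in ovary, and PADI6 was listed at 0 against 148.

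**Figure D3:**
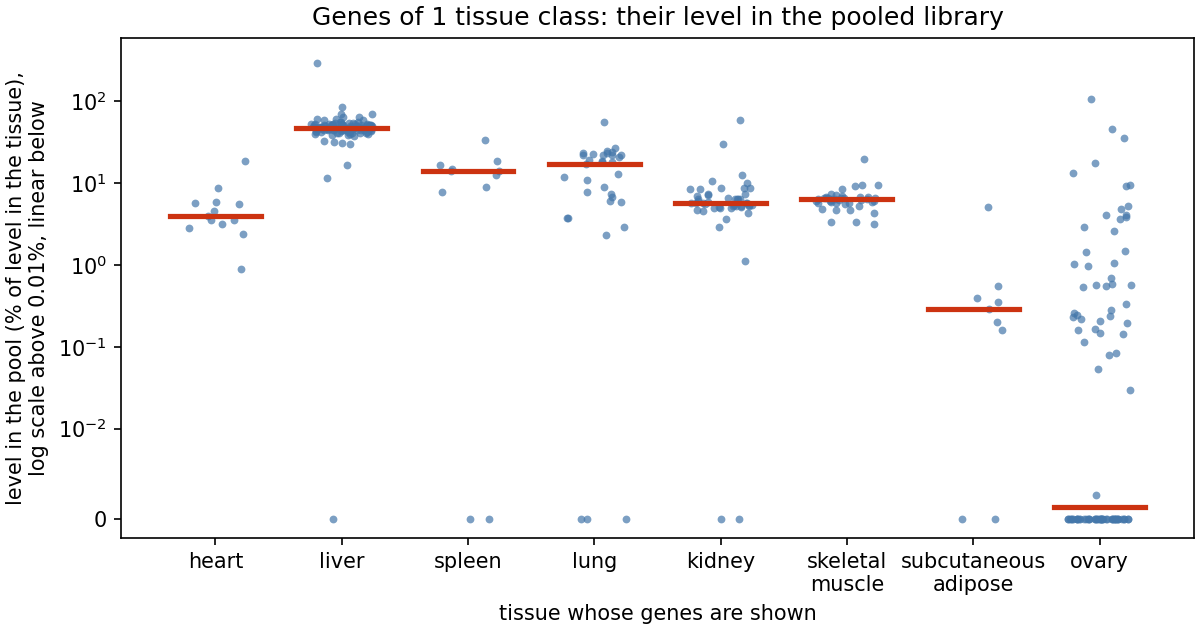
Level in the pool as a percentage of the level in the tissue (vertical axis, log scale above 0.01% and linear below), for genes expressed in a single tissue class, with each point 1 gene. Liver genes centre on 47.6% and ovary genes on 0.00133%.

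Departures from the fitted mixture were small for most genes: 95.4% of 15768 genes lay within 2-fold of it, with a robust SD of 0.21 on the log2 scale. By a departure of at least 2-fold, 426 genes were higher in the pool than fitted and 295 lower. The largest departures upwards included genes of the nervous system: MOBP (67.3 FPKM against a fitted 0.0219), SNAP25 (50.3 against 0.173), GFAP (26.5 against 0.271) and MBP (142 against 7.22). They encode proteins of myelin, of synapses and of astrocytes, and each was above its level in every single tissue. Of the 5 largest departures downwards, ATP8, ND2, KEF22_t15 and KEF22_r02 lie on the mitochondrial genome, where 9 of 13 protein genes were at 0 in at least 5 libraries, and the remaining gene was TRAPPC5 (0.0728 against 15.5). Rescaling to a sum of 1000000, which also shrinks the pseudocount and filter relative to the values, took the counts to 696 higher and 602 lower, whereas rescaling to the mean sum left them at 422 and 292. The ovary weight moved from 4.37% to 1.02% when the fit was made on unweighted FPKM and to 1.99% when it was read from enriched genes, and the kidney weight on unweighted FPKM was 0.697%.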

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

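No paired analysis was possible because each tissue had 1 library and the labels carry no animal identifier. The alternatives were fixed ahead unless said otherwise. Counts and shares within 1.5 times the reported value were called the same, and a similarity when the nearest library stayed. The share of the 10 highest genes, the genes in exactly 1 tissue, the similarity of the libraries, the liver weight of the pool and the number of lists past the percentile in their own tissue stayed the same by this limit, with at most 2229 genes in exactly 1 tissue and at least 29 lists. At a detection level of 5 FPKM, 7207 genes per library (median) and 2941 genes in all 9 tissues were detected. The count of enriched genes was 1965 at a fold of 3, 502 at a fold of 10, 1713 and 537 with pseudocounts of 0.1 and 5, and 2000 by a tau index of 0.85. With a pseudocount of 0.1, 1024 genes were higher in psoas, 345 in longissimus, 589 in heart and 333 in skeletal muscle, and with a pseudocount of 5 the counts were 141, 77, 133 and 113. Rescaling to a sum of 1000000, which also shrinks the pseudocount and filter relative to the values, gave 1639 genes in psoas and, in the pool, 696 higher and 602 lower. Median-of-ratios scaling gave 496 genes in longissimus, and centring on the median gave 228 in psoas, 397 in longissimus and 219 in heart. A difference threshold of 2 left 58 genes in psoas and 39 in longissimus, a threshold of 1 gave 1268 in heart and 490 in skeletal muscle, and a departure of 2 left 115 genes higher and 66 lower in the pool. A filter at 5 FPKM left 125 genes in longissimus and 245 higher in the pool. Stricter thresholds and filters count fewer genes by construction, and for the scalings and pseudocounts the cause was not tested. Of list percentiles in their own tissue, 172 of 180 alternatives kept the call, 6 lost it and 1 gained it. The slow-fibre list in skeletal muscle turned to percentile 2.26 when the highest other class was subtracted. For 7 of the 12 slow-fibre genes heart was at least 4-fold above each muscle in FPKM + 1, so their differences turn negative by construction. The change in percentile was not tested beyond this. For psoas minus longissimus 179 of 188 alternatives kept the call, and for heart minus skeletal muscle 146 of 164 did, where gluconeogenesis turned to percentile 98.5 with the mean of the list (the cause was not tested). All 100 alternatives for the 20 named genes of either comparison kept direction and threshold. Of the pool weights other than liver, 69 of 75 alternatives stayed and 6 moved, with ovary at 2.58% and adipose tissue at 0.331% on square roots. Detected genes of a library moved in 7 of 40 cases and enriched genes of a class in 32 of 112. Alternatives chosen after seeing the data left out mitochondrial genes, genes at 0, liver-enriched genes or ovary, or rescaled to the mean sum, which gave 815 genes in psoas. With genes above 0 in both muscles the counts were 469 and 186, without liver-enriched genes 488 and 201, and with genes above 0 in heart and both muscles 299 and 176. Without ovary the adipose weight was 2.72%. Depth limits the low values: with no counts, no interval could be given for any of them.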

Other observations

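The tests of explanations for the nervous system and ovary genes of the pool and for liver genes in other libraries were chosen after the result was seen, whereas the list percentiles were planned.

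Genes often used as references differed widely between the tissues. GAPDH ran from 339 FPKM in lung to 34563 in longissimus dorsi, and ACTB, the cytoplasmic actin gene, from 62.3 in longissimus dorsi to 1009 in spleen. The ribosomal protein gene RPL4 ran from 241 in liver to 1005 in spleen. CEBPA, JUNB and IER2 were listed at 0 in all 10 libraries, which can be failed estimates and does not show that they are not expressed.

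The muscles of these young pigs still held transcripts of developmental myosins. MYH3 and MYH8, the embryonic and perinatal heavy chain genes, stood at 41.5 and 51.3 FPKM in psoas and at 27.8 and 65.5 in longissimus, against 0.219 and 0.0102 in heart. The satellite cell gene PAX7 was at 1.33 and 1.06, and 0 elsewhere among the single tissues. MSTN, which encodes the growth inhibitor myostatin, stood at 2.18 in psoas and 5.73 in longissimus. The interferon-induced gene IFI6 was highest in liver (1302), and MX1 was similar in liver and spleen (98.8 and 96.8). Of 9 neutrophil genes 4 were highest in lung, where S100A9 and S100A12 were enriched (85.4 and 42.8), and 4 in spleen, and the list passed percentile 97.5 in spleen (100) but not in lung (94.6).

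In the pool MOBP, SNAP25, GFAP and MBP, genes of the nervous system, stood far above every single tissue. Lists of neurone, oligodendrocyte and astrocyte markers, kept free of the genes already named in the pool, gave 30 matched genes, of which 26.7% were 2-fold above the highest tissue, against 0.799% of all genes, which argues against unstable estimates of single genes. Peripheral nerve is argued against by 8 Schwann cell markers, whose median departure from the fitted mixture was 0.0125. The median departure of the 30 markers was 1.19, so RNA from the central nervous system in the pool is a candidate explanation. It was -0.13 to 0.01 for 9 lists of other tissues outside the table. Their median pool levels were 0 to 0.34 FPKM, against 7.69 for the markers, which holds their departures near 0, so they are no reference matched for level. The test by median departure was first set as the pool minus the highest tissue, gave -0.12, and was replaced after this was seen because 22 of the 30 markers reach 1 FPKM in a tissue of the table, while 6 of 11 neurone, 2 of 9 astrocyte and 0 of 10 oligodendrocyte markers passed 2-fold.

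Genes found in ovary alone were nearly missing from the pool, although ovary is on its label. Their median was 0.00133% of the ovary level (upper quartile 0.574%) against a fitted weight of 4.37%, which argues against ovary at that weight, although 147 ovary-enriched genes at 10 FPKM or more, which other tissues may share, stood at a median of 2.07%. At that fitted weight, levels too low to be seen do not account for it, since 78.3% of the 23 genes expected at 1 FPKM or more were under 0.1. Other forms of the fit gave ovary weights of 1.02% to 2.58%, at which this was not tested. Ovary tissue lacking only oocytes is argued against by the granulosa and stroma genes FSHR, AMH, AMHR2, INHA and LHX9, whose median was 0. Of these, 3 are among the genes found in ovary alone, and the other 2, AMH and INHA, stood at 0 and 0.444%. LHX9 alone came from the stroma list, so ovary lacking whole follicles could not be tested. Leaving ovary out of the fit gave 455 genes higher and 264 lower than fitted, against 426 and 295, which decides neither way, so a pool without ovary, or with ovary lacking follicles, stays open, as does a biological difference between animals.

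Liver transcripts stood in adipose tissue at a near-constant fraction of their liver level, at a median of 0.306% over 20 genes selected to be under 0.03% of liver outside adipose tissue, longissimus dorsi and the pool. For these 20 genes, expression by adipose tissue is argued against by the robust SD of their log2 ratios, 0.338, against 0.118 in the pool. For those above 0 it was 0.838 in lung (6 genes), 0.840 in ovary (9) and 1.99 in kidney (10). The 66 other liver-enriched genes spread by 3.34 to 4.32 in 6 tissues, 1.33 in longissimus and 0.997 in adipose tissue. They are the genes not under 0.03% of liver in those 6 tissues, so their spread there is partly set by selection and is no reference for the 20. For the 66, expression by adipose tissue stays open. Material from the pool is argued against by 6 lung-only genes, whose adipose level as a share of the pool was 0.0967 times that of the liver-only genes. A small share of liver material in the adipose library is a candidate explanation, tested by the 100% of these genes above 0.1% of liver, which is close to the pattern itself and so a weak test. In longissimus 19 genes were above 0, at a median of 0.0669%, with 3 above 0.1%, and the robust SD of 0.765 leaves expression by that muscle open. Tissue carried over and reads passed between libraries were not told apart, and no biological explanation beyond own expression was tested.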
